A study of Mus musculus with 6 samples.

How the data were processed

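RNA from the lungs of 6 female SCID mice was sequenced as paired-end reads on an Illumina instrument, per the labels' protocols. The authors deposited 1 table with a column per library and 24054 gene rows. Its values are a TMM-normalized signal, as the name of the deposited table states. They were taken as TMM-normalized CPM on a linear scale, with column totals from 964931 to 1022663. Bowtie2 2.1.0, RSEM 1.2.15, edgeR and the mouse build mm10 are named in the submitters' processing notes, without their roles. The annotation, the filters and the use of strand are not given in the sources used here, so reads of overlapping antisense genes cannot be assigned with certainty. Of the gene symbols 27 had turned into dates, 5611 rows were 0 in every library, and 0 rows were of mitochondrially encoded genes. Rat ELT3 cells share much sequence with mouse, and reads from them cannot be told from mouse reads in these values.

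In each column every value was a whole multiple of 1 step, so whole reads were recovered (100% of values within 0.001 of a whole number). The totals were 5101413 to 9358820 reads per library. Chi-square per degree of freedom between libraries of a group was 9.21 to 58.55 (6 pairs), where counting noise alone gives about 1 and separate mice are expected to exceed it. The labels do not say whether the mice were handled on separate days, and no batch is given.

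The group of each library was taken from its treatment label. Before the data were examined, the test, the alternatives, 51 gene lists and the rule for naming genes were fixed. Genes with a mean of at least 1 over all 6 libraries were kept (14159), log2(value + 1) was taken, and groups were compared with limma 3.58.1 in R 4.3.3 (intensity trend, two-sided moderated test, Benjamini-Hochberg adjustment, threshold 0.05). Fold changes on the log2(value + 1) scale understate those of low genes. Lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01. The named genes are the 12 on each side with the smallest unadjusted p whose samples did not overlap and whose mean level was at least 5, since no gene passed, predicted genes and pseudogenes left out. For lists, up to 4 members with the smallest unadjusted p could be named, and for cell type lists also the highest-expressed member. The 9 fixed genes could be named as well. Not every gene that this rule allowed is reported. Gm1987, Ccl21a, Malat1 and Rn45s were added after their values were seen.

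The alternatives were pseudocounts of 0.5 and 0.1, no filter, a filter at 5, a common median, quantile normalization, no trend, robust shrinkage, sample weights (limma arrayWeights), an added log2 fold of at least 1, edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 on the recovered reads, each replicate left out, and, for lists, an estimated correlation and fry. Leaving out both libraries that stood apart, or fitting a term for them, was added after seeing the data.

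The steps were tested on simulated data. With 200 genes changed among reads drawn with the spread of all 6 libraries, limma on 14159 genes recovered 42% of genes changed by a log2 fold of 1 and 99% of those changed by 2, with 6 false calls. With 2 libraries a group and the spread of the other 4 libraries it recovered 70% and 99%, with 18 false calls. Genes were drawn independently here too, and the choice of the 4 libraries was not modelled. For camera, a first version of the simulated test left no spread between libraries and was replaced by one with each gene's own spread. In that one a shift of 0.5 in 1 list was called in 3 of 3 lists tried, with 0 other lists called. It draws genes independently, so it says nothing about genes that move together.

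Sequence shared between genes was measured as the share of a gene's 50-base words that occur in transcripts of another gene of GENCODE M21, on a fixed sample of the words. Of the tested genes 99.1% were matched by symbol, and Gm1987 and Rn45s were not.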

Results

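The lungs of 6 female SCID mice were profiled by RNA sequencing, 3 mice in each of 2 groups. Both groups had received extracellular vesicles (EVs), small membrane particles shed by cells, by tail vein. The EVs carried the tetraspanins CD9, CD63 and CD81 and came from neural progenitors of E15.5 mouse embryos. In one group the progenitors were wild type (WT EV), and in the other they lacked Tsc1 (Tsc1-null EV), a subunit of the complex that restrains the growth kinase mTORC1. After 48 h each mouse was given rat ELT3 cells intravenously, a cell line used as a model of lymphangioleiomyomatosis, and the lungs were taken 72 h later. The comparison asks which lung transcripts differ with the genotype of the EV donor cells. The labels number the samples separately, so each library is taken as 1 mouse. No lungs without EVs or without ELT3 cells were analysed here, so every value is relative to WT EV.

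The WT EV libraries held 8222269, 6565182 and 8079325 reads assigned to genes, and the Tsc1-null EV libraries 5101413, 9358820 and 9092830. Values are given as TMM-normalized CPM, mean ± SD over 3 mice, and changes as log2 fold of value + 1, Tsc1-null EV over WT EV, ± SE. Of 14159 genes tested, 971 were higher in all 3 Tsc1-null EV lungs than in all 3 WT EV lungs and 881 were lower in all 3, together 13.1% where chance gives 10%. That 10% is an average over the 10 splits of the 6 libraries into 3 and 3. The share was not computed for the other splits, so the excess cannot be weighed. WT EV replicate 2 and Tsc1-null EV replicate 1 stood apart from the other 4 libraries. Their median correlations with the other libraries were 0.963 and 0.942, against 0.980 to 0.982 elsewhere. The nuclear long noncoding RNA Malat1 stood at 15673 and 30060 in these 2 libraries, against 1609 to 2819 in the others, and the ribosomal RNA precursor Rn45s at 10881 and 13776, against 3293 to 6120.

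No single gene passed the test between Tsc1-null EV and WT EV lungs, and the genes named here are those with the strongest evidence among genes whose samples did not overlap. On the higher side stood Lcn2, an iron-sequestering protein of innate defence, at 57.2 ± 17.3 in WT EV and 153.7 ± 32.9 in Tsc1-null EV lungs (n = 3 each; log2 fold 1.44 ± 0.26, adjusted p = 0.721). Hspa1a, an inducible HSP70 chaperone, stood at 48.8 ± 18.6 and 197.7 ± 90.9 (log2 fold 1.96 ± 0.37), and Ugt1a6a, a glucuronidating enzyme, at 11.1 ± 1.51 and 27.7 ± 3.19 (log2 fold 1.24 ± 0.18). On the lower side stood Ttn, the giant sarcomere protein titin, at 36.2 ± 3.83 and 14.9 ± 3.19 (log2 fold -1.24 ± 0.20), and Stk4, a kinase of the Hippo pathway, at 118.8 ± 2.51 and 70.5 ± 8.72 (log2 fold -0.75 ± 0.15). Dbp, a clock-controlled transcription factor, stood at 131.1 ± 22.0 and 66.2 ± 17.9 (log2 fold -1.0 ± 0.23).

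The other named genes on the higher side were Srp54b, Spata18, Olfml2a, Fam167a, Aacs, Col5a3, Col8a2, Cebpb and Tmprss4, with log2 folds from 0.61 for Cebpb to 1.54 for Spata18. Col5a3 and Col8a2 encode collagen chains, and Aacs activates acetoacetate for lipid synthesis. The others on the lower side were Plcb1, Ccdc85a, Hs3st1, Arhgap29, Fmnl2, St8sia4, Ranbp6, Meis1 and Aff3, with log2 folds from -0.96 for Plcb1 to -0.63 for Arhgap29. Limma called 0 of 14159 genes at an adjusted p under 0.05, with 930 at an unadjusted p under 0.05 where chance gives 708. The 708 is an average, and where genes move together a count can lie far from it. edgeR called 0 of 13873 genes (962 unadjusted), and DESeq2 called 11, of which 7 were higher and 4 lower (973 unadjusted). Besides Gm1987, the DESeq2 calls were Hspa1a, Lcn2, Ugt1a6a, Srp54b, Fam167a, Spata18, Ttn, Stk4, Arhgap29 and Ccdc85a. With weights estimated for each sample (0.21 to 4.19), limma called 583 genes higher and 467 lower, and without the 2 libraries standing apart it called 12 higher and 13 lower, an alternative chosen after seeing the data. Ugt1a6a, Srp54b and Hspa1a share 52.6%, 88.4% and 60.3% of their 50-base words with other genes, so their own levels are uncertain.

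**Figure D1:**
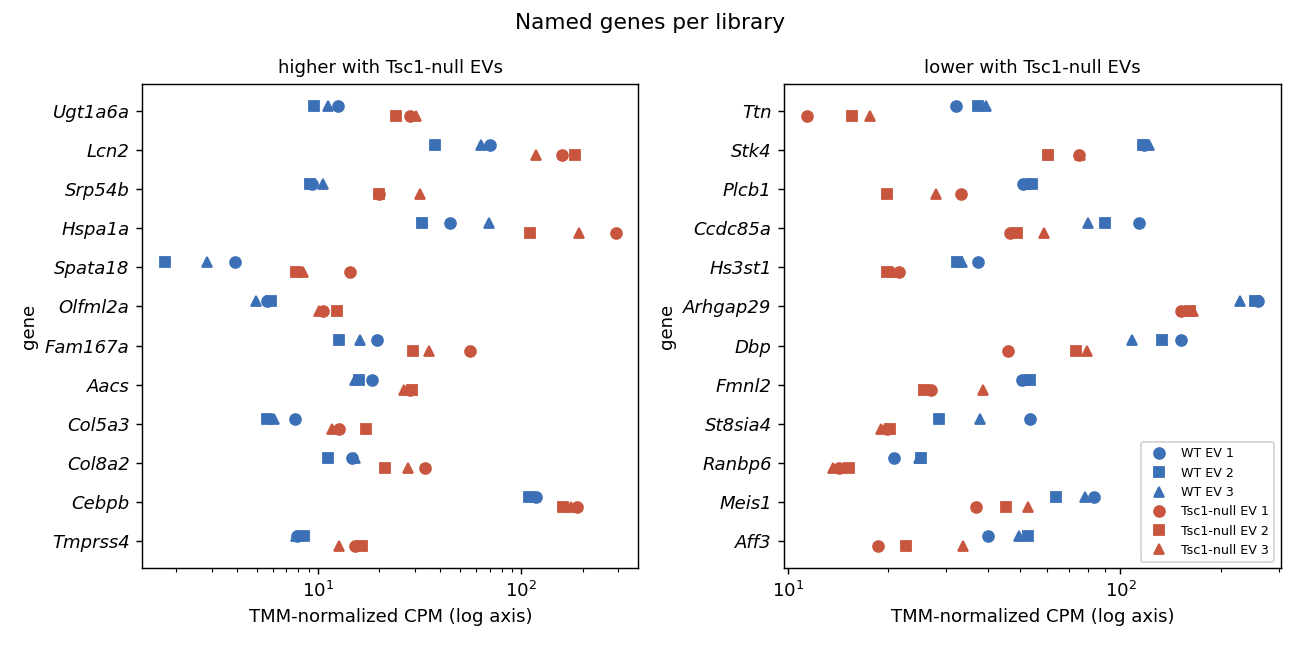
Each point is 1 library; the horizontal log axis gives the TMM-normalized CPM, and the rows are the 12 named genes on each side. Lcn2 lay between 118.4 and 183.6 in the Tsc1-null EV lungs and between 37.6 and 70.4 in the WT EV lungs; none of these genes passed limma's test.

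In genome build mm10 (GRCm38, GENCODE M21), Lcn2 lies on chromosome 2 from 32384633 to 32388252 on the minus strand, and Ttn on chromosome 2 from 76703980 to 76982547, also on the minus strand. Hspa1a lies on chromosome 17 from 34969190 to 34972156 on the minus strand, and Dbp on chromosome 7 from 45705088 to 45710203 on the plus strand. All of these are annotated as protein-coding genes, and values are totals over each gene.

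Of the genes fixed for their link to the experiment, Cd63 was higher in all 3 Tsc1-null EV lungs, at 262.6 ± 27.9 and 367.0 ± 52.3 (log2 fold 0.48 ± 0.17, adjusted p = 0.721). Tsc2 was lower in all 3, at 99.8 ± 15.4 and 79.9 ± 5.20 (log2 fold -0.31 ± 0.16). Tsc1, the gene lacking in the EV donor cells, stood at 24.4 ± 7.94 and 17.9 ± 0.715, and Mtor at 28.4 ± 3.67 and 24.8 ± 8.06, with overlapping samples. Rheb, Cd9, Cd81, Actb and Prkdc, the gene altered in SCID mice, overlapped as well, with log2 folds from -0.17 for Cd81 to 0.23 for Actb. None of these 9 genes passed.

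Among the 48 gene lists tested, markers of ciliated airway cells and of the cell cycle lay highest with Tsc1-null EV. All 18 ciliated markers had a log2 fold above 0, with a median of 0.71 (camera adjusted p = 7.49e-10; adjusted p = 0.717 with an estimated correlation). Dnah9, a motor of ciliary beating, stood at 21.6 ± 6.01 and 44.9 ± 15.3, and Tekt1, a ciliary microtubule protein, at 24.6 ± 3.08 and 40.2 ± 12.6. Tppp3, the highest-expressed member, was at 543.6 ± 69.05 and 627.4 ± 162.2, with overlapping samples. Of 26 cell cycle genes 25 were above 0, with a median of 0.60 (camera adjusted p = 1.68e-08; adjusted p = 0.717 with an estimated correlation). Top2a, a topoisomerase of dividing cells, stood at 13.7 ± 10.5 and 33.7 ± 7.43, and Mcm6, of the replicative helicase, at 9.97 ± 6.02 and 18.8 ± 2.23. The ciliated level of Tsc1-null EV replicate 1, which stood apart, was 1.42 above the WT EV mean, against 0.40 and 0.22 in its group. The cell cycle level of WT EV replicate 2, which stood apart, was 0.68 below that mean (-0.68), against 0.65 and 0.03 in its group. In the Tsc1-null EV libraries it was 0.51, 0.74 and 0.59, so the groups overlapped. Reads from the rat ELT3 cells cannot be told from mouse reads, so a share of them in this list cannot be excluded. Without the 2 libraries standing apart the medians were 0.13 for the ciliated list and 0.32 for the cell cycle. The ciliated median was 0.33 without Tsc1-null EV replicate 1 alone, and the cell cycle median was 0.26 without WT EV replicate 2 and 0.96 without WT EV replicate 1.

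The lists of lipid synthesis, alveolar type 2 cells and fibrillar collagens were also on the higher side. The sterol and fatty acid synthesis list had 21 of 24 members above 0 and a median of 0.31 (camera adjusted p = 2.96e-06; adjusted p = 0.717 with an estimated correlation). Cyp51, a lanosterol demethylase, stood at 28.5 ± 3.37 and 46.5 ± 6.15, and Sqle, squalene epoxidase, at 27.7 ± 4.62 and 44.0 ± 10.4. The alveolar type 2 list, of the surfactant-making cells, had 13 of 14 members above 0 and a median of 0.39 (camera adjusted p = 0.000109; adjusted p = 0.717 with an estimated correlation). Abca3, the surfactant lipid transporter, stood at 178.7 ± 20.2 and 282.0 ± 60.2, and Chil1 at 477.4 ± 139.4 and 878.0 ± 201.7. Sftpc, the highest-expressed member, was at 19000 ± 2660 and 21810 ± 8303, with overlapping samples. The fibrillar collagen and matrix list had 20 of 24 members above 0 and a median of 0.31 (camera adjusted p = 0.00113; adjusted p = 0.801 with an estimated correlation). Col6a3, a collagen VI chain, stood at 105.7 ± 10.4 and 155.0 ± 24.2, and Fbln2, fibulin 2, at 22.0 ± 3.97 and 37.3 ± 8.85, while Dcn, the proteoglycan decorin, was at 262.7 ± 18.9 and 211.4 ± 27.6. Without the 2 libraries standing apart the medians of these lists were 0.25, 0.49 and 0.45. The fibrillar collagen list no longer passed without WT EV replicate 2 (median 0.19, adjusted p = 0.0978), Tsc1-null EV replicate 2 (0.13, adjusted p = 0.231) or Tsc1-null EV replicate 3 (0.27, adjusted p = 0.0809), and its median was 0.64 without Tsc1-null EV replicate 1 and 0.47 without WT EV replicate 1. The alveolar type 2 median was 0.25 without WT EV replicate 2 and 0.23 without Tsc1-null EV replicate 2.

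5 further lists passed camera on the higher side. Glycolysis had 14 of 17 members above 0 and a median of 0.21 (camera adjusted p = 0.0027), with Pgk1 at 121.8 ± 11.5 and 167.7 ± 24.5 and Ldha at 310.8 ± 48.9 and 428.0 ± 50.1 (adjusted p = 0.717 with an estimated correlation). Heat shock proteins had a median of 0.16 (camera adjusted p = 0.0405; adjusted p = 0.717 with an estimated correlation). Hspa1a and Dnajb1, an HSP40 cochaperone at 73.5 ± 15.8 and 121.3 ± 13.4, passed when adjusted over the list alone (2 of 15 members). That adjustment does not allow for the number of lists, and over all genes tested both had a limma adjusted p of 0.721. Club and secretory cell markers had a median of 0.42 but a mean of 0.14 (camera adjusted p = 0.0115), with Scgb3a2 at 1209 ± 293.2 and 1950 ± 693.4 (adjusted p = 0.801 with an estimated correlation). Nuclear oxidative phosphorylation subunits had a median of 0.11 (camera adjusted p = 0.0168), and monocyte and interstitial macrophage markers one of 0.18 (camera adjusted p = 0.0289), with Cd14 at 33.7 ± 11.6 and 62.0 ± 21.3 (adjusted p = 0.811 with an estimated correlation for both lists). Without the 2 libraries standing apart the club list lay on the lower side by camera, with a median of 0.08, and neither it nor the heat shock list (median 0.04) passed. The club list also did not pass without WT EV replicate 2 (0.28), Tsc1-null EV replicate 1 (0.24) or Tsc1-null EV replicate 2 (0.43), and stood at 0.65 without Tsc1-null EV replicate 3. Heat shock proteins did not pass without WT EV replicate 1 (0.12) or 2 (0.10), or Tsc1-null EV replicate 1 (0.09) or 3 (0.24). Oxidative phosphorylation subunits did not pass without WT EV replicate 1 (0.10) or 2 (0.06) or Tsc1-null EV replicate 2 (0.01). Monocyte and macrophage markers did not pass without WT EV replicate 2 (0.02) or Tsc1-null EV replicate 2 (0.05) or 3 (0.09), and stood at 0.29 without WT EV replicate 1, 0.45 without Tsc1-null EV replicate 1 and 0.28 without the 2 libraries standing apart.

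On the lower side stood markers of mesothelium, the cell layer covering the lung, and of endothelium, heart muscle and fat. Mesothelial markers had 11 of 12 members below 0 and a median of -1.31 (camera adjusted p = 1.5e-06; adjusted p = 0.717 with an estimated correlation). Gpm6a stood at 165.6 ± 55.1 and 72.9 ± 26.5, and Wt1, a mesothelial transcription factor, at 10.3 ± 5.61 and 3.54 ± 2.18. Krt19, the highest-expressed member, was at 221.6 ± 44.5 and 233.3 ± 46.1, with overlapping samples. Endothelial markers had 20 of 21 members below 0 and a median of -0.40 (camera adjusted p = 2.69e-06; adjusted p = 0.717 with an estimated correlation). Egfl7 stood at 348.6 ± 37.3 and 238.5 ± 21.7, and Sox17, an arterial transcription factor, at 42.2 ± 6.26 and 30.2 ± 3.89. Pecam1, the highest-expressed member, was at 919.3 ± 170.4 and 726.5 ± 188.9, with overlapping samples. Heart muscle genes had a median of -0.95 and adipocyte genes one of -0.88 (camera adjusted p = 5.23e-06 and 9.39e-05; adjusted p = 0.717 with an estimated correlation for both). Tnnt2, cardiac troponin T, stood at 106.9 ± 32.0 and 57.7 ± 22.6, and Adrb3, the beta 3 adrenergic receptor, at 14.8 ± 4.21 and 6.80 ± 1.96. The level of Tsc1-null EV replicate 1 against the WT EV mean was -2.92 for the mesothelial, -0.87 for the endothelial, -1.84 for the heart and -1.46 for the adipocyte list. The groups overlapped in all 4 lists. Tsc1-null EV replicate 3 lay at -0.30 for mesothelial markers, against -0.43 in WT EV replicate 3. It lay at 0.01 for endothelial markers, against -0.22 in WT EV replicate 2. Tsc1-null EV replicate 2 lay at -0.05 for heart and -0.23 for adipocyte genes, against -0.67 and -0.68 in WT EV replicate 2. Without the 2 libraries standing apart the 4 medians were -0.26, -0.24, -0.62 and -0.87, and without Tsc1-null EV replicate 1 alone they were -0.65, -0.14, -0.36 and -0.46. The adipocyte median was -0.38 without WT EV replicate 3.

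6 further lists passed camera on the lower side. Angiogenesis and lymphangiogenesis factors had 20 of 22 members below 0 and a median of -0.33 (camera adjusted p = 3.56e-05), with Vegfa at 539.7 ± 106.3 and 390.9 ± 57.3 (adjusted p = 0.717 with an estimated correlation). Erythroid genes had 12 of 13 members below 0 and a median of -0.34 (camera adjusted p = 0.00436), with the haemoglobin gene Hba-a1 at 5100 ± 886.7 and 2667 ± 883.8 (adjusted p = 0.746 with an estimated correlation). Pericyte markers had a median of -0.21, interferon-stimulated genes -0.19 and smooth muscle markers -0.13 (camera adjusted p = 0.0168, 0.0168 and 0.0278; adjusted p = 0.811 with an estimated correlation for all 3). Of the interferon-stimulated genes, Gbp3 stood at 39.5 ± 6.08 and 25.4 ± 4.84 and Ifit2 at 31.9 ± 1.44 and 23.7 ± 4.75, while Usp18 was at 25.0 ± 3.82 and 35.8 ± 5.11. The level of Tsc1-null EV replicate 1 was -0.97 for the erythroid, -0.78 for the pericyte and -0.57 for the interferon list. Without the 2 libraries standing apart the medians of the pericyte and interferon lists were -0.06 and 0, that of the angiogenesis list was -0.20, and the pericyte, interferon and smooth muscle lists no longer passed. Without Tsc1-null EV replicate 1 alone the angiogenesis median was -0.10, and the erythroid (-0.14), pericyte (-0.02), interferon (0.01) and smooth muscle (-0.08) lists did not pass. Without WT EV replicate 1 the erythroid (-0.32), pericyte (-0.22), interferon (-0.11) and smooth muscle (-0.05) lists did not pass, nor did the pericyte list without WT EV replicate 3 (-0.17) or the smooth muscle list without Tsc1-null EV replicate 3 (-0.13). The medians farthest from 0 with 1 library left out were -0.55 for angiogenesis (Tsc1-null EV replicate 3), -0.60 for erythroid (WT EV replicate 2), -0.40 for pericyte (Tsc1-null EV replicate 2), -0.32 for interferon (Tsc1-null EV replicate 3) and -0.32 for smooth muscle (Tsc1-null EV replicate 2).

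Circadian clock genes had a median of -0.20 (camera adjusted p = 0.0358; adjusted p = 0.717 with an estimated correlation), and 4 of the 19 passed when adjusted over the list alone, in opposite directions. Dbp and Hlf, output factors of the clock, were lower, Hlf at 56.5 ± 5.22 and 29.3 ± 10.9. Arntl, which encodes the core activator BMAL1, and Nfil3, a repressor of the same output sites, were higher, at 3.76 ± 1.04 and 7.30 ± 1.09 and at 5.62 ± 1.43 and 10.6 ± 1.78. None of the 4 overlapped between the groups. Over all genes tested, each of the 4 had a limma adjusted p of 0.721. The list did not pass without WT EV replicate 2 (median -0.09, adjusted p = 0.282) or Tsc1-null EV replicate 2 (-0.15, adjusted p = 0.278), and its median was -0.34 and -0.37 without WT EV replicates 1 and 3. The circadian, heat shock, glucocorticoid and immediate early lists had been fixed as lists of handling. Sample numbers 1348 to 1350 were all WT EV and 1351 to 1353 all Tsc1-null EV. Any handling order that followed these numbers cannot be told apart from the EV genotype, and the hour of collection was not among the values analysed.

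Of the lists that did not pass, 4 held 1 gene each that passed when adjusted over the list alone. This gene was Lcn2 in the neutrophil, acute inflammation and glucocorticoid lists and Cebpb, at 114.1 ± 4.72 and 174.6 ± 13.6, in the integrated stress response list. Over all genes tested, both had a limma adjusted p of 0.721. The premetastatic niche list had a median of 0.04 (camera adjusted p = 0.323), with S100a4, a calcium-binding protein, at 43.3 ± 17.1 and 98.0 ± 19.7. Of the other matrix lists, crosslinking and remodelling enzymes had a median of -0.08 with 18 of 26 members below 0 (camera adjusted p = 0.795), and basement membrane one of -0.05 with 10 of 18 below 0 (camera adjusted p = 0.683). Both medians were 0.12 without the 2 libraries standing apart (camera adjusted p = 0.00574 and 0.273; adjusted p = 0.57 and 0.788 with an estimated correlation). Components of the mTORC1 pathway had a median of -0.07 (camera adjusted p = 0.411), EV markers 0.02 (0.81), LAM lesion markers -0.07 (0.892) and neural progenitor genes -0.13 (0.634).

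**Figure D2:**
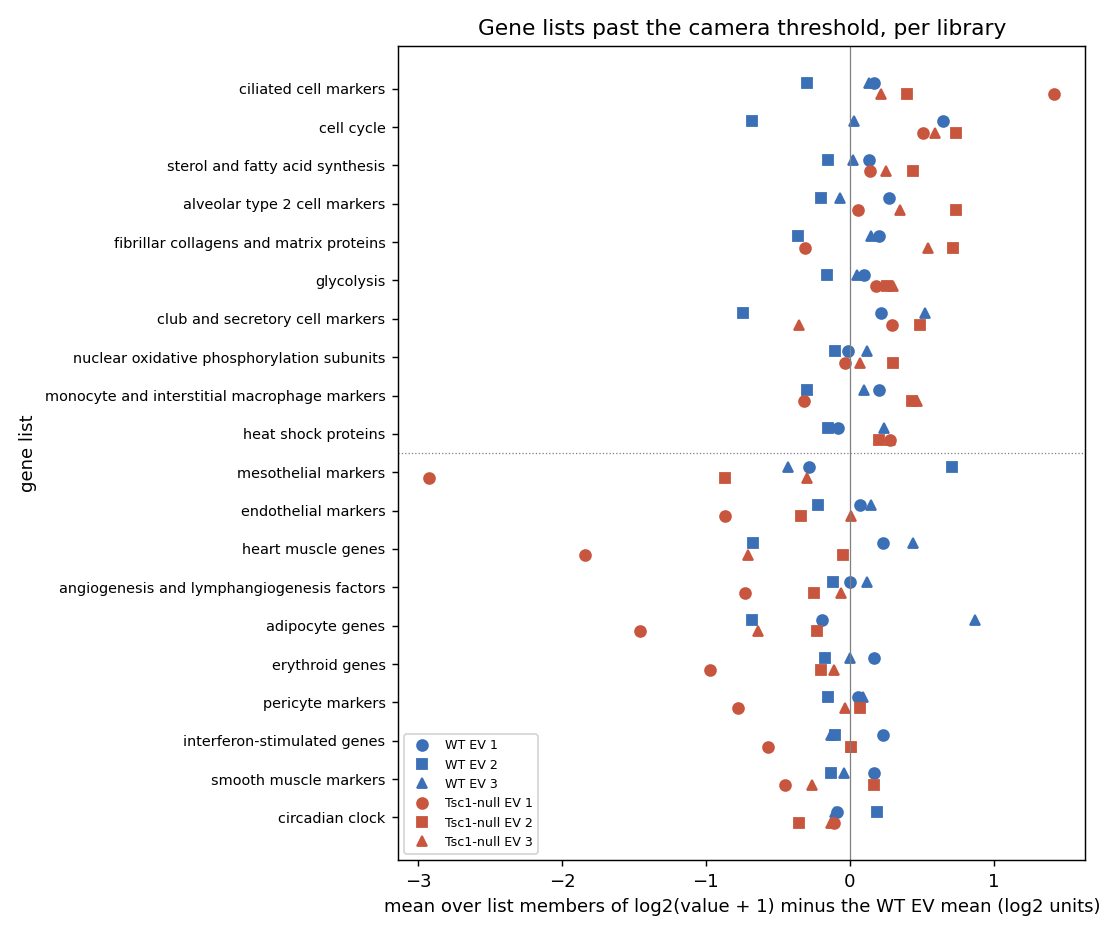
Each point is 1 library's mean log2 level of a list's measured genes minus the mean of the 3 WT EV libraries, for the 10 lists above and the 10 below the dotted line that passed camera. Tsc1-null EV replicate 1 lay at 1.42 for ciliated and at -2.92 for mesothelial markers, farther out than any other library.

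Of the 51 lists fixed, 48 had at least 5 measured members, and 20 of these passed camera with its preset correlation of 0.01, 10 on each side. With an estimated correlation 0 passed (smallest adjusted p = 0.717), as with fry, which asks whether a list's genes move one way. Without the 2 libraries standing apart 23 lists passed at the preset correlation, 15 of them among the 20 and on the same side. With an estimated correlation none passed in that fit (smallest camera adjusted p = 0.57).

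Gm1987, a predicted gene, had the smallest adjusted p of all genes and was chosen after its values were seen. It stood at 2.04 ± 2.52 in WT EV and 99.2 ± 36.4 in Tsc1-null EV lungs (log2 fold 5.27 ± 0.52, adjusted p = 0.067). Ccl21a, the lymphatic chemokine CCL21, went the other way, at 87.7 ± 24.0 and 18.2 ± 27.7 (log2 fold -3.68 ± 1.12, adjusted p = 0.721). Their sum was 89.7 ± 26.3 and 117.0 ± 8.85 (log2 fold 0.42 ± 0.21, adjusted p = 0.721). In Tsc1-null EV replicate 1 both were read, at 57.5 for Gm1987 and 50.1 for Ccl21a. Gm1987 passed without Tsc1-null EV replicate 1 (adjusted p = 0.0181) and without WT EV replicate 3 (adjusted p = 0.00312).

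**Figure D3:**
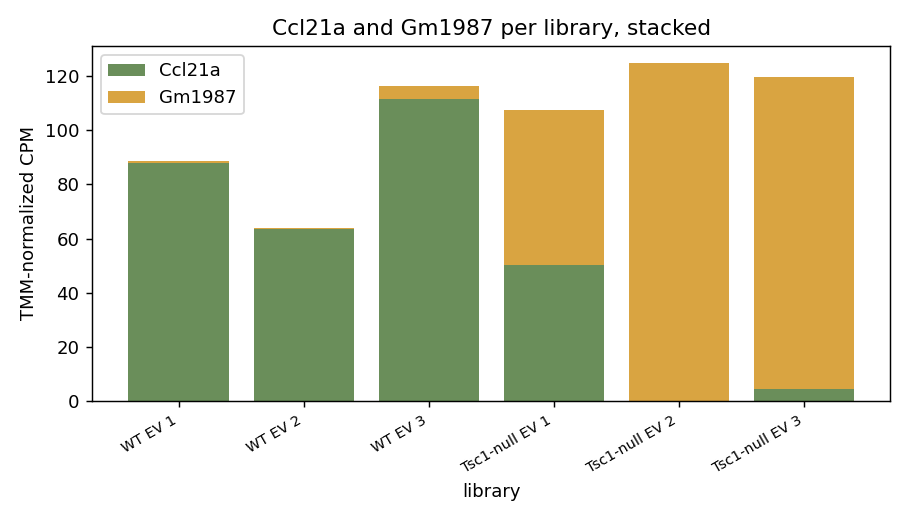
Stacked bars give the TMM-normalized CPM of Ccl21a and Gm1987 in each library, starting at 0. The sum lay between 63.9 and 116.5 in the WT EV lungs and between 107.7 and 124.9 in the Tsc1-null EV lungs.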

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

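Leaving out both libraries that stood apart, and the term for them, were chosen after the results were seen, and the other alternatives before. The count of 0 genes stayed at 0 with pseudocounts of 0.5 and 0.1, no filter, a filter at 5, a common median, quantile normalization, no trend, robust shrinkage and edgeR. An added log2 fold of at least 1 could only leave the count at 0, since it removes calls and adds none. The count was 11 with DESeq2 and 1050 with sample weights. Those weights ran from 0.21 for Tsc1-null EV replicate 1 to 4.19 for WT EV replicate 3 and 3.95 for Tsc1-null EV replicate 2, so that fit rests mostly on 1 library a group, and 50.9% of its calls did not overlap between groups. It was 25 without both libraries standing apart, 21 with edgeR on the same 4 libraries and 1 (Gm1987) with a term for them. Leaving out each replicate gave 0 to 2 genes. These were Btg3 without WT EV replicate 1, Gm1987 without WT EV replicate 3, Gm1987 and Ccl21a without Tsc1-null EV replicate 1, and Atp6v0c-ps2 without Tsc1-null EV replicate 3. All of these are among the genes described below, read above 20 in 1 library and below 0.5 in another. Btg3 was 0 in both remaining WT EV libraries and Atp6v0c-ps2 was 0 in both remaining Tsc1-null EV libraries. Those groups thus had no spread of their own in these fits. Of the fixed genes 1 passed with sample weights and 0 otherwise. The cause was not tested. The 20 lists became 0 with an estimated correlation, 0 with fry's directional test and 0 with its mixed test, which allow for genes that move together. With each replicate left out 16 to 23 lists passed, 14 to 19 of them among the 20. The club list went to the lower side without both libraries standing apart (median 0.08). Directions turned for 6 genes, none past the threshold where turned. Rheb was at 0.003 with quantile normalization. With single replicates left out Rheb ran from -0.198 to 0.07, Cd9 from -0.013 to 0.213, Cd81 from -0.418 to 0.292, Prkdc from -0.424 to 0.194 and Zbtb16 from -0.147 to 0.738. Cd81 was at 0.136 with sample weights, and 0.208 and 0.211 (edgeR) without both. Mtor was at 0.017 and 0.037, and Prkdc at 0.262 and 0.194, without both. No paired analysis was possible because the groups share no replicate numbers in the labels. The depth limits low genes most, since 1 read is worth 0.108 to 0.2 in these units.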

Other observations

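The tests of copies and of tissue makeup below were chosen after the result was seen, and those of depth, nuclear RNA and other splits before. The fits without both libraries standing apart were chosen after seeing the data.

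Without both libraries that stood apart, limma called 25 genes, 12 higher and 13 lower, and no group of genes was tested for among them. Col1a2 and Col3a1, chains of the main fibrillar collagens, had log2 folds of 0.94 ± 0.15 (adjusted p = 0.0425) and 0.95 ± 0.16 (adjusted p = 0.0476), and Mmp2, a gelatinase, 0.96 ± 0.14 (adjusted p = 0.0281). Gpnmb, a transmembrane glycoprotein, had 1.15 ± 0.14 (adjusted p = 0.0104) and S100a4 1.01 ± 0.14 (adjusted p = 0.0209). Zbtb16, a glucocorticoid-responsive gene, had 1.22 ± 0.19 (adjusted p = 0.0425), and Plagl1, an imprinted transcription factor, -1.55 ± 0.18 (adjusted p = 0.00701). Only S100a4 and Gpnmb come under the rule for naming genes, the others were chosen after their values were seen, and with all 6 libraries their adjusted p ran from 0.721 to 0.945. In simulated data with 200 changed genes this design gave 18 false calls, beside 70 and 99 recovered genes at log2 folds of 1 and 2. That simulation drew genes independently and did not model the choice of the 4 libraries. Its false calls therefore cannot be set against the 25 calls made without both libraries standing apart. Lists that passed camera there but not with all 6 libraries included premetastatic niche factors (median 0.25, adjusted p = 0.000682; adjusted p = 0.57 with an estimated correlation) and glucocorticoid targets (median 0.26, adjusted p = 4.02e-05; adjusted p = 0.649 with an estimated correlation). Immediate early genes were on the lower side (median -0.20, adjusted p = 7.64e-05; adjusted p = 0.57 with an estimated correlation).

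The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 0 genes and the highest other 1. For lists the real split gave 20 and the highest other 29. The 4 splits with both libraries standing apart on one side gave 20 to 29. Apart from the real split, the splits with these libraries on opposite sides gave 11 to 18. Both libraries were picked from the same values for standing apart, so that contrast is no separate evidence of a structure of the samples. Lists thus passed under every split, so the 20 lists do not by themselves point to the EV genotype. With sample weights the real split gave 1050 genes and the highest other 27. As many results as in the real split came from 10, 5 and 1 of the 10 splits, the real one included.

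Gm1987 was higher and Ccl21a lower with Tsc1-null EV. A change of the summed Ccl21a and Gm1987 values by a log2 fold of 1 is argued against, since the 95% interval of the summed fold ended at 0.91. The limit of 1 was set after the values were seen. Other copies such as Gm21541 were not in the sum, so total Ccl21 transcripts were not measured. A candidate explanation is reads shared between near-identical copies, since the summed values differed by a log2 fold of 0.42, only just within 2 SE of 0, and Ccl21a shares 69.6% of its words with Gm21541. Genes read above 20 in 1 library and below 0.5 in another numbered 16, of which 14 were matched. Of these 64.3% shared at least 50% of their words with another gene, against 1.8% of other genes (Fisher's exact p = 4.9e-13). With a limit of 3 reads in place of 0.5, also set after the values were seen, such genes numbered 17 and the share was 60.0%. Ccl21a itself was among them, and partners such as Eif3j1 and Eif3j2 were counted separately, so that p cannot be taken at face value. Gm1987 was not matched, so its sharing with Ccl21a was not measured. Some of these genes switched within a group, such as Eif3j1 at 0.12, 130.81 and 121.16 in WT EV replicates 1 to 3. Switches of this kind thus also occurred without following the groups. Whether that of Gm1987 and Ccl21a followed the groups by chance was not tested, and Gm1987 was picked for its small p. A variant between the mice at this locus stays open, since the reads were not analysed here.

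WT EV replicate 2 and Tsc1-null EV replicate 1 stood apart from the other 4 libraries. Shallower sequencing is argued against, since with every library thinned to 5101413 reads the gap in median correlation was 0.0161, against 0.0169 before and a range of 0.0025 among the other 4. More nuclear RNA may contribute, as Malat1, Meg3 (14.99 and 13.83, against 1.94 to 3.42) and Kcnq1ot1 (694.8 and 454.3, against 128.5 to 220.7) were high in both, though these were seen before the test. Neat1, seen then too, was high in WT EV replicate 2 alone (1437 and 455.5, against 272.3 to 446.3). For 8 others fixed for the test, the mean log2 level was 0.72 in WT EV replicate 2, above every other library, and 0.01 in Tsc1-null EV replicate 1, which left the lower of the 2 at -0.23 against the highest of the other 4. For Tsc1-null EV replicate 1 this explanation and others, such as handling of the tissue, cannot be told apart, since these transcripts disagree.

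Ciliated markers were higher and mesothelial markers lower with Tsc1-null EV. The makeup of the piece taken for Tsc1-null EV replicate 1 and a response of the lung to the EV genotype cannot be told apart. Without that library the medians kept 46.9% and 49.1% of their size, which decides nothing, since it was picked for lying farthest out. What remained, 0.33 and -0.65, passed camera at its preset correlation (adjusted p = 0.000111 and 0.000427). That fit was not run with an estimated correlation, under which neither list passed with all 6 libraries (camera adjusted p = 0.717 for both). Without both libraries standing apart the medians were 0.13 and -0.26 (adjusted p = 0.0109 and 0.0327; adjusted p = 0.679 and 0.714 with an estimated correlation), so whether a difference beyond that library exists stays open.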
